A study of Arabidopsis thaliana with 4 samples.

How the data were processed

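Small RNAs bound to AGO1 or AGO2 were sequenced from Arabidopsis leaves, with 1 library for each of 4 groups. Per the labels' protocols, 4-week-old plants were used and leaves were taken 14 h after inoculation. The mock inoculum was 10 mM MgCl2, and the R2 inoculum was a Pseudomonas syringae pv. tomato strain with the effector gene avrRpt2. AGO1 was precipitated from wild-type Col-0 with an antibody to AGO1, and AGO2 from plants that carry an HA-tagged AGO2 transgene. The labels name the antibody for AGO2 both as one to the HA tag and as one to AGO2, and which was used is left open here. Each precipitate came from 3 g of leaf, and libraries were amplified by 22 PCR cycles, per the labels.

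The deposited values are raw read counts per distinct trimmed sequence, made by the authors without an alignment step named in the sources used here. Per the series' README, which serves as the file header, the authors collapsed identical reads, kept reads that began with AG, and trimmed the 3-prime adaptor. The README also says that 1 library was first shortened to 36 nt, under a name that matches none of the 4 sample names. The AGO1 and AGO2 libraries carried different 3-prime adaptors, per the deposited adaptor list. No molecular identifiers were used, so intervals and floors cover counting error only.

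Reads of 18 to 28 nt were kept, and each count was scaled to reads per 1000000 of these reads (RPM). A list of 106 sequences (74 miRNA guides, 28 star strands and 4 tasiRNAs) and all lists of families were written from general knowledge before the data were examined, along with the comparisons and the other processing settings to try. A star strand is the partner of the guide in the miRNA duplex, and a tasiRNA is a trans-acting small interfering RNA. Of the list, 15 sequences were in no library and were left out. A read counted for a listed sequence only if identical to it. Locus tags of MIR genes came from the RefSeq gene table of assembly TAIR10.1, used for names only. Base positions are counted from 1 at the 5-prime end of the small RNA.

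With 1 library per group there is no replicate spread, so no p-value is given. Each ratio of RPM carries an exact 95% Clopper-Pearson interval on its 2 counts, and each share an exact 95% binomial interval. A share of 0 also carries the limit that 3 counts of the total would give. A count of 0 was set to a floor of 3 counts in that library and the ratio was then given as a bound. The named sequences in each comparison were, among listed sequences with at least 100 reads in the 2 libraries together, the 10 highest and the 10 lowest ratios whose interval left out 1. miR393b-3p and its guide miR393a,b-5p were named in every comparison. The rule also named loci, which needed a genome. Lists of sequences were the guides starting with U, the guides starting with A, the star strands, the tasiRNAs, and guides and tasiRNAs grouped as development, auxin, nutrient and stress, silencing, PPR and TAS, defence, and other. Each list's median log2 ratio was given a percentile among 10000 random lists of the same size. Each random member was drawn from the 100 unlisted sequences nearest in mean abundance, without adaptor reads, copies of miR159b-3p and sequences absent from 1 of the 2 libraries. The percentile describes these libraries and belongs to the median of members present in both.

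Adaptor reads were those that held any 12-nt word of the adaptors. Alternatives were scaling to listed reads, median-of-ratios factors over the 44 listed sequences present in all 4 libraries, reads of 20 to 25 nt, matching of the first 18 nt, and minimums of 20 and 500 reads. Profiles were also taken over distinct sequences and without the 10 most abundant sequences. Scaling without adaptor reads, and without adaptor reads and miR159b-3p with its copies of up to 2 changed bases, was added after the data were seen. So were all start forms, which take in reads with bases 4 to 18 of a listed sequence and a start shifted by up to 3 bases, where that 15-nt core belongs to 1 listed sequence. The tRNA motifs, the tables of changed and lost bases, and the split of star strands by first base were also chosen then. Lists were also summarised as means and with 0.5 reads added to each count. Matching to a genome, and with it the profile of genome-matched reads, the rRNA and organelle classes, the list of loci and the choice between single and multiple matches, was not run here. The computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.

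The ratio and list steps were tested on simulated counts made from the 2 AGO2 libraries, with 8560 sequences for the ratio step, of which some were changed by known folds, and 8374 for the list step. The simulated counts held random (Poisson) counting error only, the error that the interval assumes. They thus test the computation, and hold no spread from PCR or between plants. The interval held the true ratio for 95.7% of unchanged sequences, for 96.7% of those changed 2-fold, and for 91.8% of the 61 changed 4-fold. The direction was called for 76.6% of sequences changed 1.5-fold, 91.8% of those changed 2-fold and 100% of those changed 4-fold. Of 100 simulated lists of 12 sequences shifted 2-fold, 100 lay above the upper limit of the random lists, against 1 of 100 unshifted lists. Those random lists also held counting error only, so power against the real spread of unlisted sequences was not tested.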

Results

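AGO1 and AGO2 are Argonaute proteins, which bind small RNAs and use them to find target transcripts. The series asked which small RNAs are bound to AGO2 after infection of Arabidopsis leaves with the bacterium Pseudomonas syringae. It held 4 libraries: AGO1 mock, AGO1 R2, AGO2 mock and AGO2 R2, where R2 marks inoculation with the strain that carries avrRpt2, an effector gene recognised by the plant's resistance protein RPS2. There was 1 library per group, so every difference lacks a replicate check, and intervals cover counting error only. The libraries held 19823015, 20334204, 7616350 and 20017232 reads in that order. Of these, 14963294, 14220744, 7359962 and 19202159 reads were 18 to 28 nt long. Adaptor sequence made up 47.1% of such reads in AGO1 mock and 36.6% in AGO1 R2, against 0.396% in AGO2 mock and 0.722% in AGO2 R2.

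The first question was whether each protein held small RNAs of the length and 5-prime base known for it, AGO1 being known for U and AGO2 for A. AGO1 reads began most often with U, at 35.8% (35.8 to 35.9) in mock and 37.4% (37.4 to 37.5) in R2, and at 57.3% and 52.2% without adaptor reads. Over distinct sequences U did not lead in AGO1 R2, where G began 30.1% and U 27.6%, or 30.3% and 28.9% without adaptor reads and miR159b-3p. AGO2 was led by a single miRNA: miR159b-3p (TTTGGATTGAAGGGAGCTCTT, MIR159B, AT1G18075), a regulator of GAMYB-like transcription factors. It made up 72.4% of AGO2 mock reads and 46.1% of AGO2 R2 reads, against 1.62% and 1.28% in AGO1. Because miR159b-3p begins with U, A led only 21.5% (21.5 to 21.6) of all AGO2 mock reads and 39.2% (39.1 to 39.2) of AGO2 R2 reads. Without adaptor reads and miR159b-3p, A began 82.7% (82.6 to 82.7) of AGO2 mock reads and 76.7% (76.7 to 76.7) of AGO2 R2 reads, against 15.8% and 16.8% in AGO1.

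**Figure D1:**
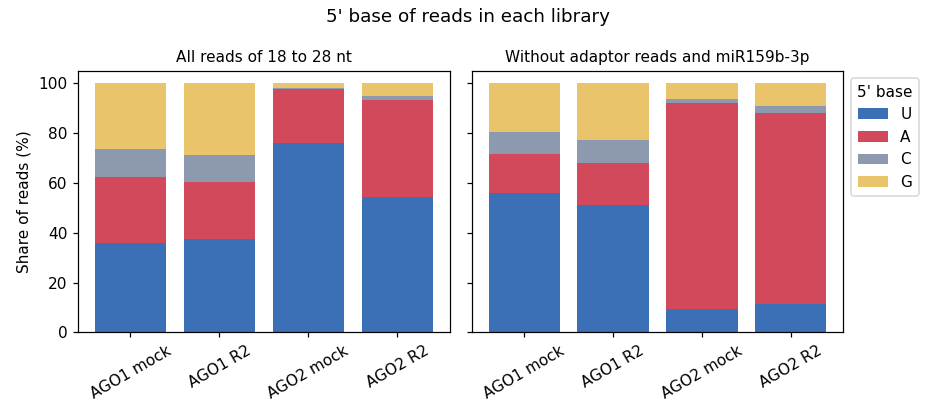
Share of reads (percent, y axis) by 5-prime base in each of the 4 libraries (x axis), for all reads of 18 to 28 nt (left) and without adaptor reads and miR159b-3p (right). In the right panel A makes up 82.7% of AGO2 mock and 76.7% of AGO2 R2 reads, and U makes up 55.8% of AGO1 mock and 51.0% of AGO1 R2 reads.

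Reads of 21 nt, the usual miRNA length, made up 86.4% (86.4 to 86.4) of AGO2 mock and 75.1% (75.1 to 75.1) of AGO2 R2 reads, against 25.5% (25.5 to 25.6) and 25.6% (25.6 to 25.7) in AGO1. The 21-nt shares without adaptor reads and miR159b-3p were 48.9% and 52.3% in AGO2 and 28.1% and 26.7% in AGO1. There 20-nt reads made up 26.9% of AGO1 mock and 27.8% of AGO1 R2, so 21 nt did not lead in AGO1 R2. Of these 20-nt reads in AGO1 R2, miR158a-3p alone made up 1224445 of 2446016. Over distinct sequences without adaptor reads and miR159b-3p, 21 nt led in AGO1 R2, at 21.1% against 14.9% for 20 nt. In that remainder A began 63.5% of 20-nt, 78.3% of 21-nt, 92.2% of 22-nt and 96.3% of 24-nt reads in AGO2 mock, and 57.0%, 77.1%, 90.4% and 86.2% in AGO2 R2. In AGO1 mock A began 7.74% of 21-nt, 25.9% of 22-nt and 33.9% of 24-nt reads. The 24-nt class, which is mostly made up of siRNAs that guide DNA methylation and is known from AGO4, made up 17.99% of this remainder in AGO2 mock and 14.9% in AGO2 R2, against 6.19% and 6.78% in AGO1. Over all reads the direction turned, at 4.66% and 7.53% in AGO2 against 9.85% and 8.58% in AGO1. Without adaptor reads alone the values were 4.67% and 7.58% in AGO2 and 5.97% and 6.61% in AGO1.

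The next comparison asked which small RNAs lay in AGO2 more than in AGO1 of mock leaves. Reads identical to a listed sequence were counted, and values with all start forms also took in reads that share its bases 4 to 18 and start up to 3 bases away. All 4 measured guides that begin with A and 6 of 9 star strands were at least 2-fold higher in AGO2, and 31 of 36 guides that begin with U were at least 2-fold lower. Among the exceptions were the guides miR159b-3p and miR168a,b-5p, which begin with U and were 44.7-fold (44.5 to 44.8) and 3.79-fold (3.53 to 4.06) higher. With all start forms miR168a,b-5p was 2.44-fold (2.30 to 2.59) higher. The star strands miR846-5p and miR396a-3p were 34.1-fold (11.5 to 167) and 1.63-fold (1.58 to 1.68) lower, or 54.9-fold (26.5 to 137) and 2.66-fold (2.58 to 2.73) with all start forms. The direction of 2 of these depended on scaling: miR168a,b-5p was at 0.709 when scaled to listed reads, and miR396a-3p at 10.5 with median-of-ratios factors and 1.21 without adaptor reads and miR159b-3p. Listed reads in AGO2 mock were mostly miR159b-3p, at 5325936 of 5401977. miR393b-3p (ATCATGCGATCTCTTTGGATT, MIR393B, AT3G55734), the star strand of the miRNA that targets TIR1-type auxin receptors, had 17732 reads in AGO2 and 0 in AGO1, at least 12017-fold higher. This bound was 2251 when scaled to listed reads, 6377 without adaptor reads and 205849 with median-of-ratios factors. Its guide miR393a,b-5p had 3 reads in AGO2 and 994 in AGO1, 163-fold lower (55.6 to 792). miR165a,b-3p and miR166a-g-3p, which target HD-ZIP III genes of leaf polarity, had 1 against 93764 reads and 51 against 420103 reads. The ratio was 4052-fold lower (3081 to 5442) for miR166a-g-3p, or 2763-fold with all start forms, and the ratio was 2.17e-05 (5.49e-07 to 0.000121) for miR165a,b-3p. With all start forms the ratio of miR165a,b-3p was 4.21e-05 (5.10e-06 to 0.000152).

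Other star strands with high AGO2 to AGO1 ratios in mock leaves were miR398b-5p at 1716 (307 to 67854), or 2.98 (2.71 to 3.28) with all start forms, miR391-3p at 78.1 (63.4 to 97.3) and miR396b-3p at 76.1 (66.3 to 87.6), or 28.5 (26.2 to 31.0) with all start forms. The partner of miR396b-3p targets growth-regulating factors. Among guides that begin with A, miR840-5p was at least 640.4-fold higher, miR390a,b-5p, the trigger of TAS3 tasiRNAs, was 38.8-fold higher (33.5 to 45.1), miR172a,b-3p, which targets AP2-like genes, 34.8-fold higher (20.7 to 63.1) and miR408-3p, which targets copper proteins, 15.3-fold higher (13.7 to 17.1). With all start forms the ratio was 126 for miR840-5p, 18.2 for miR390a,b-5p and 2.46 for miR408-3p. The guide miR161.2, which begins with U, was at least 71.8-fold higher, or 1.72 (1.32 to 2.23) with all start forms. On the AGO1 side were miR162a,b-3p, which targets DCL1, at 607-fold lower in AGO2 (417 to 921), or 12.4-fold (11.8 to 13.1) with all start forms, and miR158a-3p, with 1062388 AGO1 reads, at 175-fold lower (169 to 181), or 167-fold with all start forms. The SPL regulator miR156a-f-5p had 0 AGO2 reads and was at least 383-fold lower, or 24.1-fold (18.8 to 31.2) with all start forms, and the ARF-targeting tasiRNA TAS3 5D7, also with 0 reads, at least 400.4-fold lower. The listed form of miR161.1, with 84 AGO2 reads, was 145-fold lower (117 to 182), but with all start forms its ratio lay on the other side of 1, at 1.25 (1.23 to 1.27). miR825 and the ARF regulator miR160a-c-5p each had 1 AGO2 read of the listed form, with ratios of 0.00232 (5.86e-05 to 0.0129) and 0.00210 (5.3e-05 to 0.0117). For miR160a-c-5p the direction turned with all start forms, to 3.20 (3.05 to 3.35) from 4271 AGO2 reads.

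Of 53 listed sequences measured in mock leaves, 13 were at least 2-fold higher in AGO2 and 36 at least 2-fold lower. By first base, 3 of 36 guides starting with U were at least 2-fold higher and 31 at least 2-fold lower, with a median log2 ratio of -5.11. All 4 measured guides starting with A were at least 2-fold higher, with a median of 5.12. Of 9 star strands, 6 were higher and 1 was lower, with a median of 3.52 at percentile 96.9 of matched random lists. Percentiles were 10.9 for guides starting with U and 88.0 for guides starting with A. With zero counts at their bound the medians were -5.19, 5.20 and 3.86. Both measured tasiRNAs were lower (TAS3 5D7 above, TAS1 siR255 at 22.9-fold). The development list had 2 of 13 higher and 11 lower (median -4.79, percentile 29.9, -5.99 at the bound), auxin 1 of 7 higher and 5 lower (-5.09, percentile 30.5, -6.05 at the bound), and nutrient and stress 1 of 4 higher and 3 lower (-3.40, percentile 57.7). Silencing had 1 of 3 higher and 2 lower (-2.40, percentile 60.1), PPR and TAS 1 of 4 higher and 3 lower (-5.85, -4.80 at the bound, and with all start forms 0.32, or -1.57 at the bound), defence 0 of 2 higher and 2 lower (-7.18), and the other guides 1 of 11 higher and 9 lower (-4.96, percentile 27.1, -4.88 at the bound). The median over all listed sequences was -4.17, and it was -3.20 without adaptor reads and miR159b-3p and -0.0756 with median-of-ratios factors, which gave 20 higher and 20 lower. These factors were taken from the listed sequences themselves, which moves the median and these counts toward balance by construction. The directions of the highest and lowest sequences above were the same under each scaling, unlike those of miR168a,b-5p and miR396a-3p. Antibody, plant genotype and 3-prime adaptor differed along with the protein, so their parts in these ratios cannot be told apart.

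**Figure D2:**
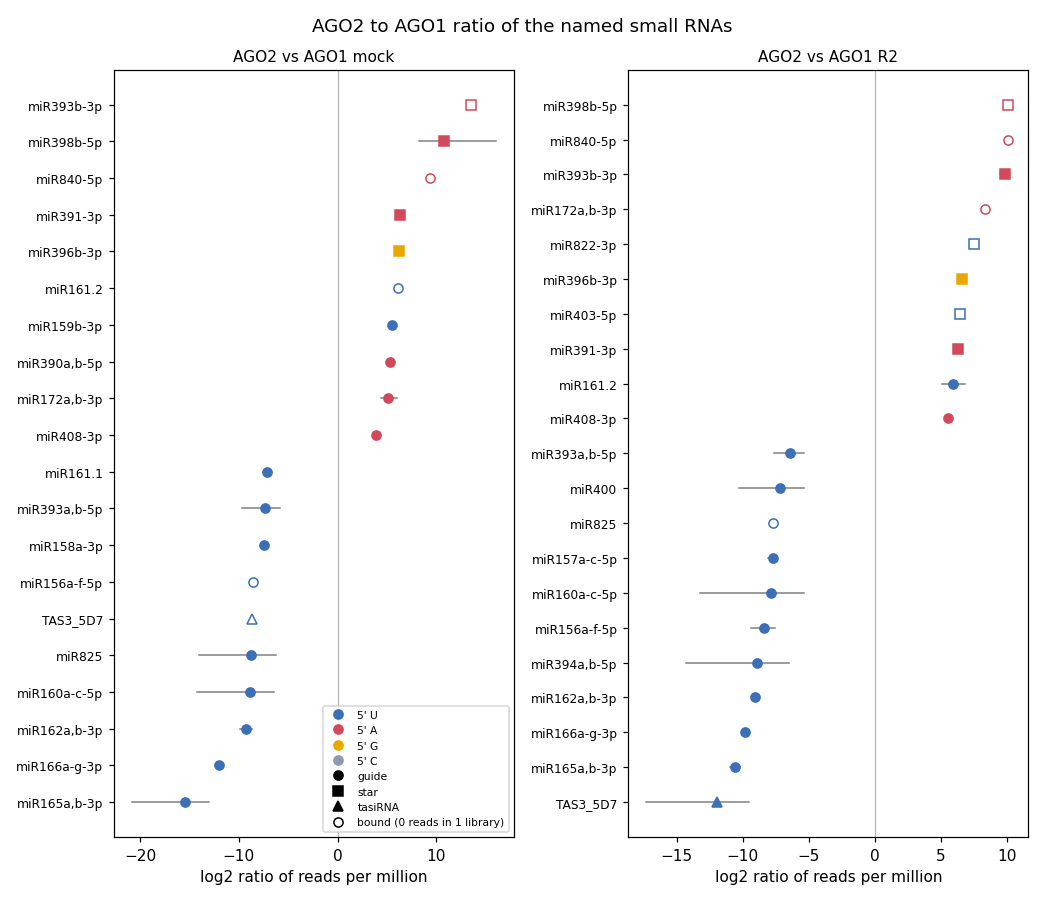
AGO2 to AGO1 log2 ratio of RPM (x axis) of the named small RNAs (y axis) in mock (left) and R2 (right) leaves; color gives the 5-prime base, shape the strand, lines exact 95% counting intervals, and open symbols bounds. Counts are of identical sequences. Named sequences on the AGO1 side all begin with U, and miR393b-3p lies at 13.55 (bound) in mock and 9.82 in R2.

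In infected leaves the same question gave a like picture, with miR393b-3p again among the highest ratios. It had 69558 AGO2 reads and 57 AGO1 reads, 904-fold higher (697 to 1193), or 683-fold (550.4 to 859) with all start forms, while miR393a,b-5p was 84.1-fold lower (42.3 to 196). miR398b-5p and miR840-5p, both at 0 reads in AGO1, were at least 1079.5-fold and 1062-fold higher, and miR172a,b-3p at least 315-fold higher. miR398b-5p was at 3.81 (3.58 to 4.06) with all start forms, from 1183 AGO1 reads. TAS3 5D7 had 1 AGO2 read and 2990 AGO1 reads, a ratio of 0.000248 (6.27e-06 to 0.00138), or 0.00292 (0.00164 to 0.00483) from 15 AGO2 reads with all start forms. miR165a,b-3p was 1538-fold lower (1211 to 1985) and miR166a-g-3p 888-fold lower (811 to 975), or 997-fold and 649.8-fold with all start forms.

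Further star strands on the AGO2 side were miR822-3p at least 179-fold higher, miR403-5p, partner of the miRNA that targets AGO2 itself, at least 86.4-fold higher, miR396b-3p at 94.2-fold (84.4 to 105), or 46.9-fold (43.6 to 50.6) with all start forms, and miR391-3p at 77.5-fold (65.4 to 92.6). The guides miR161.2 and miR408-3p were 57.9-fold (33.7 to 109) and 46.1-fold (40.1 to 53.2) higher, and miR408-3p was at 6.12 with all start forms. Lower in AGO2 were miR162a,b-3p at 529-fold (439 to 645), or 6.09-fold (5.97 to 6.22) with all start forms, miR156a-f-5p at 331-fold (185 to 663) and the related miR157a-c-5p at 215-fold (170.3 to 276). The last 2 were, with all start forms, 22.8-fold (19.9 to 26.2) and 70.7-fold (63.0 to 79.6) lower. miR825, with 0 AGO2 reads, was at least 215-fold lower. The listed forms of miR394a,b-5p, miR160a-c-5p and miR400 had 1, 1 and 2 AGO2 reads, with ratios of 0.00201 (5.07e-05 to 0.0113), 0.00421 (0.000106 to 0.0238) and 0.00676 (0.000814 to 0.0247). With all start forms miR160a-c-5p lay on the AGO2 side here as well, at 7.14 (6.82 to 7.48).

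Of 53 measured sequences in infected leaves, 17 were at least 2-fold higher in AGO2 and 32 at least 2-fold lower, against 21 and 26 with median-of-ratios factors. Guides starting with U had 4 of 34 higher and 28 lower (median -5.04, percentile 10.5, -5.17 at the bound), guides starting with A had 4 of 4 higher (4.85, or 6.91 at the bound), and star strands had 9 of 12 higher and 1 lower (3.32, percentile 85.4, 5.76 at the bound). Both tasiRNAs were lower, with a median of -7.97. Development guides had 2 of 11 higher and 8 lower (-6.97, percentile 3.8, -6.18 at the bound), auxin 2 of 7 higher and 5 lower (-5.30, percentile 28.8), nutrient and stress 1 of 3 higher and 2 lower (-3.20, percentile 53.7) and silencing 1 of 3 higher and 2 lower (-2.47, percentile 50.4). PPR and TAS had 1 of 5 higher and 4 lower (-4.60, percentile 36.1), defence 2 of 2 lower (-4.55, or -6.15 at the bound) and the other guides 1 of 10 higher and 8 lower (-4.91, percentile 31.3, -4.70 at the bound). The median over all listed sequences was -4.23, or -3.20 with zeros at the bound, and -3.94 without adaptor reads and miR159b-3p.

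A share within 1 library needs no scaling between libraries, so star and guide reads of each pair were compared in each library. In AGO2 the star strand made up nearly all reads of the miR393b, miR396b, miR396a, miR391, miR171a and miR398b pairs. With all start forms the star share in AGO2 mock was 99.996% for miR165a, 98.3% for miR822 and 89.8% for miR166a,b, the last at 0% by exact match. For others it was lower with all start forms, as for miR403 in AGO2 mock (43.0%, against 65.0%) and miR156a in AGO2 R2 (11.5%, against 70.3%). miR393b-3p was 99.98% of its pair in AGO2 mock (99.95 to 99.997) and 99.99% in AGO2 R2, against 0 of 994 reads in AGO1 mock, which allows up to 0.302% at 3 counts (exact interval up to 0.370%), and 10.3% (7.87 to 13.1) in AGO1 R2. miR396b-3p was 99.1% (98.8 to 99.3) in AGO2 mock and 2.07% (1.80 to 2.37) in AGO1 mock. The miR391 star was 37.6% (31.5 to 44.0) of its pair in AGO1 mock and 100% in AGO2 mock, but 8.25% in AGO1 mock and 7.92% in AGO1 R2 when the first 18 nt were matched. The miR408 pair ran the other way: its star miR408-5p was 12.8% (11.7 to 14.0) of reads in AGO2 mock and 69.1% (66.4 to 71.8) in AGO1 mock, or 13.6% and 27.9% with all start forms. Both of its strands begin with A in their listed forms. With all start forms, A began 99.9% of miR408-3p reads in AGO2 mock but 17.5% in AGO1 mock. For miR408-5p these shares were 99.1% and 96.3%. The miR396a star led in both proteins, at 96.8% in AGO1 mock and 99.7% in AGO2 mock. For miR168a, miR390a and miR158a the guide led in all 4 libraries, with a star share of at most 0.993% (miR158a in AGO2 mock), or 2.55% with all start forms (miR168a in AGO2 R2).

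Pooled over 22 pairs, star reads were 76.7% (76.3 to 77.1) of pair reads in AGO2 mock and 73.1% (72.9 to 73.3) in AGO2 R2, against 1.21% (1.19 to 1.23) and 1.32% (1.299 to 1.33) in AGO1. The AGO1 shares rest mostly on 1 pair, as miR396a-3p made up 17537 of the 19997 star reads in AGO1 mock. Over the 17 pairs with unique first 18 nt, which leave this pair out, the shares were 68.6% and 62.4% in AGO2 and 0.135% and 0.208% in AGO1. The AGO2 shares lean on miR393b-3p, with 17732 of the 40404 star reads in AGO2 mock by exact match. Over the pairs with unique first 18 nt it made up 18749 of 28074 in AGO2 mock and 74914 of 109103 in AGO2 R2. Of 17 pairs with at least 20 reads in both mock libraries, 12 had a higher star share in AGO2 and 1 a lower share, beyond both intervals. In R2 these counts were 15 and 2 of 20 pairs. The star was the majority strand for 10 of 17 pairs in AGO2 mock and for 3 in AGO1 mock. These counts of pairs take miR393a and miR393b separately, although both rest on the same reads of the guide miR393a,b-5p. The pooled shares left the miR393a pair out.

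**Figure D3:**
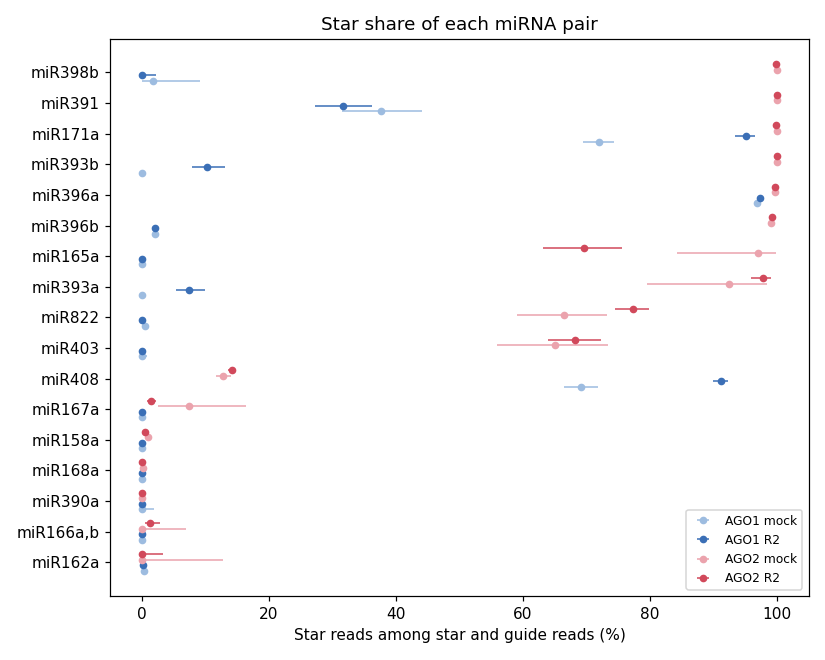
Star reads among star and guide reads (percent, x axis) for each miRNA pair (y axis) in the 4 libraries, with exact 95% binomial intervals as bars. The miR393b pair lies at 99.98% in AGO2 mock and 10.3% in AGO1 R2, and the miR408 pair at 12.8% in AGO2 mock and 69.1% in AGO1 mock.

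The series' main question was which AGO2-bound small RNAs differed after infection. miR159b-3p, with the most AGO2 reads, had an R2 to mock ratio of 0.637 (0.636 to 0.638), and 32 of 35 measured sequences had ratios above 1. Their median log2 ratio was 0.87, and it was -0.10 without adaptor reads and miR159b-3p, a shift of -0.97. Values relative to the median are therefore given as well. miR393b-3p had 2409 RPM in mock and 3622 in R2, a ratio of 1.504 (1.48 to 1.53), or 1.54 with all start forms. This was -0.28 relative to the median on the log2 scale, and the ratio was 0.768 without adaptor reads and miR159b-3p. miR393a,b-5p had 3 and 8 AGO2 reads. The star of the other miR393 gene, miR393a-3p, had a ratio of 3.83 (2.73 to 5.53), 1.07 above the median.

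The sequences with the highest ratios included several guides that begin with U and had few AGO2 mock reads. Guides starting with U made up 18 of the 35 measured sequences, and their median log2 ratio was 0.73, against 0.87 over all. miR846-5p had 3 reads in mock and 117 in R2, a ratio of 14.9 (4.99 to 73.5). The ARF regulators miR167a,b-5p and miR167d had ratios of 6.21 (4.81 to 8.14) and 5.28 (4.03 to 7.06), or 1.77 and 1.53 above the median. miR161.1 and miR161.2, which target PPR genes, had ratios of 5.69 (4.56 to 7.19) and 3.68 (3.01 to 4.54) in their listed forms. That of miR161.1 rests on 84 mock reads, and with all start forms, 35782 mock and 34139 R2 reads, its ratio lay below 1, at 0.366 (0.360 to 0.371). miR166a-g-3p followed at 3.49 (2.61 to 4.75), miR850 at 2.96 (2.42 to 3.67), miR390a,b-5p at 2.38 (2.30 to 2.47) and miR822-3p at 2.30 (1.89 to 2.81). The last 4 were at 3.23, 2.25, 2.42 and 1.65 with all start forms. The ratios without adaptor reads and miR159b-3p were 3.17 for miR167a,b-5p, 2.91 for the listed form of miR161.1 and 1.22 for miR390a,b-5p. With median-of-ratios factors the log2 ratios of miR390a,b-5p, miR822-3p and miR393b-3p were -0.10, -0.15 and -0.76.

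Of the 35 sequences, 12 were at least 2-fold higher in R2 and 0 at least 2-fold lower. These counts were 4 and 3 without adaptor reads and miR159b-3p, 4 and 5 with median-of-ratios factors, and 30 and 0 when scaled to listed reads. In AGO2 the listed reads were nearly all miR159b-3p. Relative to the median, 6 lay at least 2-fold above and 3 at least 2-fold below. The 3 measured auxin guides, both miR167 forms and miR390a,b-5p, were at least 2-fold higher, with a median log2 ratio of 2.40 at percentile 98.3 of matched random lists. Both miR167 forms belong to the same family, whereas the members of a random list were drawn separately. In 2 of the scalings above miR390a,b-5p was under 2-fold, while both miR167 forms stayed over it. The auxin median was 1.03 with all start forms, over miR160a-c-5p and miR390a,b-5p, since the miR167 forms share their core. The PPR and TAS list had a median of 2.19 over the listed forms of miR161.1 and miR161.2, and 1.02 with all start forms. Guides starting with U had 7 of 18 higher (0.73, percentile 35.4), guides starting with A 1 of 4 (0.87, percentile 48.5) and star strands 4 of 12 (0.93, percentile 57.2). Development had 1 of 7 higher (0.43, percentile 13.3), nutrient and stress 0 of 2 (0.89), silencing 0 of 3 (0.63, percentile 33.6) and the other guides 2 of 6 (0.80, percentile 45.3). No tasiRNA or defence guide reached 100 reads.

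The same question for AGO1 gave ratios on both sides of 1. miR390a,b-5p had the highest, 5.09 (4.35 to 5.99), with 190 reads in mock and 920 in R2, or 3.85 (3.45 to 4.30) with all start forms. The lowest were miR827, which targets NLA of phosphate supply, at 20.7-fold lower in R2 (10.3 to 48.6), miR171a-3p, which targets SCARECROW-like genes, at 10.2-fold lower (7.25 to 14.8) and miR160a-c-5p at 5.24-fold lower (4.46 to 6.19). These were, with all start forms, 4.98-fold (3.43 to 7.41), 9.62-fold (6.94 to 13.7) and 1.29-fold (1.22 to 1.37) lower. miR472-3p, which targets NBS-LRR resistance genes, was 3.61-fold lower (3.02 to 4.34). miR393a,b-5p was 1.90-fold lower (1.70 to 2.12), or 2.15-fold with all start forms, and its star miR393b-3p had 0 and 57 reads, under the 100 reads set for a ratio.

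Also higher in AGO1 R2 were miR400 at 3.44 (2.60 to 4.59), miR398b,c-3p, which targets superoxide dismutases, at 3.12 (2.30 to 4.28), miR408-5p at 2.69 (2.48 to 2.92), miR824-5p at 2.65 (2.27 to 3.09), miR846-5p at 2.32 (1.97 to 2.75) and miR447a,b at 2.16 (1.94 to 2.40). miR391-5p was at 2.02 (1.65 to 2.48), miR171b,c-3p at 1.88 (1.28 to 2.80) and miR168a,b-5p, which targets AGO1 itself, at 1.85 (1.72 to 1.98). Further lower sequences were miR395a,d,e, which targets sulfate assimilation genes, at 4.40-fold (2.81 to 7.15), miR847 at 3.58-fold (2.58 to 5.05), miR843 at 2.64-fold (2.44 to 2.87), miR170-3p at 2.34-fold (1.51 to 3.71) and miR825 at 1.75-fold (1.56 to 1.96). With all start forms the ratio was 4.35 (3.13 to 6.17) for miR171b,c-3p, 1.49 (1.35 to 1.63) for miR846-5p, 1.66 (1.53 to 1.79) for miR391-5p and 1.44 (1.36 to 1.53) for miR168a,b-5p. Lower by that count were miR395a,d,e at 2.04-fold (1.47 to 2.87) and miR843 at 2.13-fold (2.00 to 2.27). The abundant guides lay closer to 1, with miR158a-3p at 1.21 (0.999 without adaptor reads and miR159b-3p) and miR166a-g-3p at 0.765.

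Of 52 measured AGO1 sequences, 8 were at least 2-fold higher and 8 at least 2-fold lower, with a median log2 ratio of 0.09. Without adaptor reads and miR159b-3p these were 5, 11 and -0.19, and with median-of-ratios factors 11, 7 and 0.35. The directions of the named sequences were the same under each scaling. Guides starting with U had 5 of 39 higher and 7 lower (median 0.04, percentile 2.65), guides starting with A 1 of 2 higher (0.78), star strands 2 of 7 higher (0.63, percentile 67.3) and tasiRNAs 0 of 2 (0.47). Development had 0 of 13 higher and 2 lower (-0.22, percentile 2.16), auxin 1 of 7 higher and 1 lower (0.18, percentile 37.5), nutrient and stress 1 of 6 higher and 2 lower (-0.40, percentile 6.34) and silencing 0 of 3 either way (0.60, percentile 62.6). PPR and TAS had 1 of 4 higher (0.26, percentile 34.1), defence 1 of 2 lower (-1.33) and the other guides 3 of 10 higher and 2 lower (0.44, percentile 53.1).

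For 26 sequences measured in both proteins, the R2 to mock ratio could be set side by side. The listed form of miR161.1 had a ratio of 5.69 in AGO2 and 0.952 in AGO1, but all its start forms had 0.366 and 0.951. miR167a,b-5p had 6.21 and 1.13, and miR166a-g-3p 3.49 and 0.765. AGO1 ratios this near 1 depended on scaling, with miR161.1 at 1.14 with median-of-ratios factors and miR167a,b-5p at 0.931 without adaptor reads and miR159b-3p. miR390a,b-5p was at 2.38 and 5.09, and its AGO2 ratio was 0.933 with median-of-ratios factors. miR408-3p was at 1.76 in AGO2 and 0.582 in AGO1, and the AGO2 value was 0.898 without adaptor reads and miR159b-3p. The difference between the proteins was not tested, since each ratio rests on 2 libraries.

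**Figure D4:**
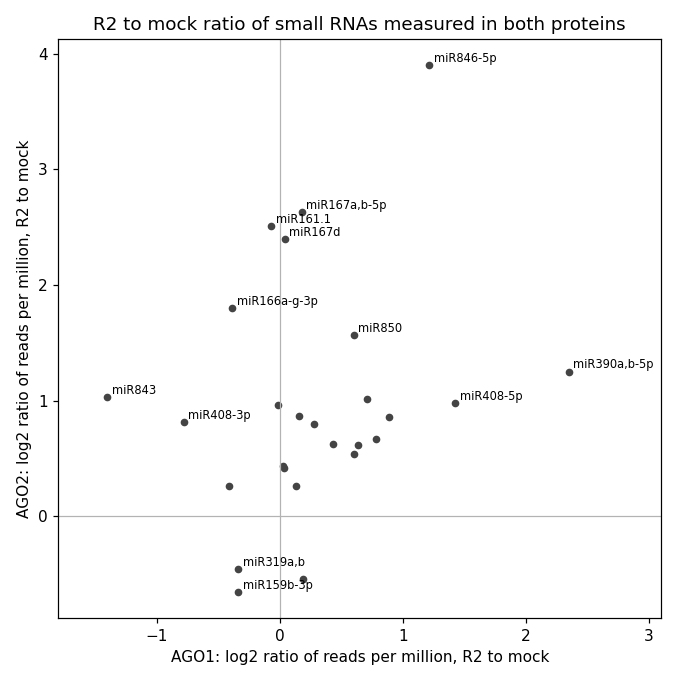
R2 to mock log2 ratio of RPM in AGO1 (x axis) and AGO2 (y axis) for the 26 small RNAs measured in both proteins, each point a small RNA. miR167a,b-5p lies at 0.18 in AGO1 and 2.63 in AGO2, and miR390a,b-5p at 2.35 and 1.25; the median of the AGO2 ratios over 35 sequences was 0.87.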

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

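Scaling without adaptor reads and miR159b-3p, counts of all start forms and the set of tRNA motifs were chosen after the values they bear on had been seen. miR843 lay above 1 in AGO2 and below 1 in AGO1. Its R2 to mock ratio was 2.04 (1.40 to 3.06) in AGO2, from 33 and 176 reads, and 0.378 (0.349 to 0.409) in AGO1, from 2318 and 833 reads. The difference was not tested, since each group had 1 library, and the AGO2 side depended on scaling. The AGO2 ratio was 0.801 with median-of-ratios factors and 1.04 without adaptor reads and miR159b-3p, against 0.454 and 0.312 in AGO1. With all start forms the ratios were 1.62 (1.54 to 1.71) in AGO2 and 0.469 (0.440 to 0.5004) in AGO1.

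Reads with a tRNA motif lie outside the comparisons and had higher shares after infection. They made up 2.55% of AGO2 R2 reads and 1.86% of AGO1 R2 reads, without adaptor reads and miR159b-3p. In the mock libraries, taken as controls, the shares were 0.258% in AGO2 and 1.03% in AGO1. The motifs were read by sequence alone, and whether the reads came from plant or bacterial tRNA was not tested.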

How the results depend on the processing

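Scaling without adaptor reads, scaling without adaptor reads and miR159b-3p, distinct sequences without both, and all start forms were chosen after the data were seen. All start forms take in reads with bases 4 to 18 of a listed sequence and a start shifted by up to 3 bases. They turned the direction of miR161.1 in AGO2 R2 against mock (log2 ratio -1.45), of miR161.1 (0.32) and miR160a-c-5p (1.68) in AGO2 against AGO1 in mock leaves, and of miR160a-c-5p (2.84) in infected leaves. The PPR and TAS median of AGO2 against AGO1 in mock leaves was 0.32 over the members present in both libraries, but -1.57 with a zero count at its bound, so its direction stays open. Under the other alternatives the named directions were the same except for 3 sequences in AGO2 R2 against mock. With median-of-ratios factors their log2 ratios were -0.10 (miR390a,b-5p), -0.15 (miR822-3p) and -0.76 (miR393b-3p), and miR393b-3p was at -0.38 without adaptor reads and miR159b-3p. The factors came from the listed sequences themselves, some with 1 AGO2 mock read, such as miR165a,b-3p and miR160a-c-5p. A change of scaling moves all ratios of a comparison by the same factor, which by construction is why medians and counts moved. For the other values the cause was not tested.

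For AGO2 R2 against mock, scaling to listed reads gave 30 sequences at least 2-fold higher and a median log2 ratio of 1.49. Of listed reads, miR159b-3p made up 5325936 of 5401977 in AGO2 mock and 8850584 of 9172534 in AGO2 R2. In AGO2 this scaling thus mostly divides by miR159b-3p. Median-of-ratios factors gave 4 higher, 5 lower and a median of -0.48. Without adaptor reads and miR159b-3p there were 4 higher, 3 lower and a median of -0.10. Matching the first 18 nt gave a median of 0.98, and a minimum of 20 reads gave 21 higher. All start forms gave 1 sequence at least 2-fold lower and medians of 1.04 for development, 1.03 for auxin, 1.08 for nutrient and stress, 0.89 for silencing and 1.02 for PPR and TAS. For AGO1 R2 against mock, the median was 0.35 with median-of-ratios factors, -0.18 without adaptor reads and -0.19 without adaptor reads and miR159b-3p, the last 2 each with 5 higher. A minimum of 20 reads gave 13 higher and 15 lower, and a minimum of 500 reads gave 5 and 3, as fewer sequences were measured. All start forms gave a tasiRNA median of 0.15.

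For AGO2 against AGO1 in mock leaves, the median was -6.59 with scaling to listed reads, -0.0756 with median-of-ratios factors (20 higher and 20 lower), -4.44 with reads of 20 to 25 nt, -3.61 with a minimum of 20 reads and -4.68 with 500. It was -5.09 without adaptor reads and -3.20 without adaptor reads and miR159b-3p. In infected leaves the values in the same order were -5.96, -1.75, -4.49, -3.20, -2.94, -4.88 and -3.94, and matching the first 18 nt gave -4.56. With all start forms the medians were -2.77 in mock and -1.28 in infected leaves, with -3.44 (-4.28 at the bound) for the other guides in mock and 3.51 (4.61 at the bound) for guides starting with A in infected leaves. The mean in place of the median gave 1.17 for star strands in AGO2 R2 against mock and -4.45 for guides starting with U in AGO2 against AGO1 in infected leaves. Adding 0.5 reads gave 8.204 for guides starting with A there, since 2 of the 4 had a count of 0. It also moved other lists with zero counts, such as star strands in infected leaves (6.41) and tasiRNAs in mock leaves (-7.79). For the auxin list in mock leaves the mean was -3.67.

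The 21-nt share, in the order AGO1 mock, AGO1 R2, AGO2 mock and AGO2 R2, was 18.9%, 19.9%, 37.3% and 53.0% over distinct sequences and 21.9%, 22.5%, 46.7% and 51.9% without the 10 most abundant sequences. It was 30.7%, 28.5%, 86.7% and 75.7% without adaptor reads, 28.1%, 26.7%, 48.9% and 52.3% without adaptor reads and miR159b-3p, and 20.5%, 21.1%, 37.7% and 53.5% over distinct sequences without both. The share of reads starting with U in AGO1 mock and R2 was 29.0% and 27.6% over distinct sequences, 31.8% and 31.8% without the 10 most abundant, 57.3% and 52.2% without adaptor reads, 55.8% and 51.0% without adaptor reads and miR159b-3p, and 31.1% and 28.9% over distinct sequences without both. G led distinct sequences in AGO1 R2, at 30.1%, or 30.3% without both. The share starting with A in AGO2 mock and R2 was, in the same order, 79.3% and 65.6%, 82.8% and 74.6%, 21.5% and 39.3%, 82.7% and 76.7%, and 80.4% and 66.1%. Matching the first 18 nt gave pooled star shares of 0.135%, 0.208%, 68.6% and 62.4% over the 17 pairs with unique starts, and all start forms gave 0.167%, 0.245%, 82.3% and 79.4%. In AGO2 mock, miR393b-3p made up 18749 of the 28074 star reads by the first 18 nt. With all start forms miR165a-5p made up 54881 of 87305 there.

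Of the named values, 49 of 73 moved with median-of-ratios factors, 42 of 77 without adaptor reads and miR159b-3p, and 32 of 66 with all start forms, beyond those named above. Scaling to listed reads moved 41 of 73, and scaling without adaptor reads 41 of 77. These counts depend on the limit set for a move, which is not given here. Alternatives that need a genome (reads that match it, single or multiple matches, and counts per locus) were not run. Depth bounds what a count of 0 can tell. A count of 0 among the 994 AGO1 mock reads of its pair allows a miR393b-3p share of up to 0.302% at 3 counts, and of up to 0.370% by the exact interval. Such limits count reads, not molecules. The lowest nonzero counts of listed sequences in AGO1 mock were 1 (miR398b-5p) and 15 (miR172a,b-3p). AGO1 R2 and AGO2 mock held counts between, such as 8 (miR827) and 5 (miR167a-3p). If a molecule gave several reads, floors and bounds at 3 reads are too tight, which was not tested.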

Other observations

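AGO2 held start-shifted forms of several miRNAs that begin with A where the listed form begins with U. For miR160a-c-5p, 99.7% of AGO2 mock reads began with A, mostly 1 base upstream, against 11.2% in AGO1 mock. The values were 97.3% and 0.0703% for miR162a,b-3p, 98.98% and 2.45% for miR850 and, in infected leaves, 59.7% and 0.103% for TAS1 siR255. A form of miR165a-5p shifted by 1 base, GAATGTTGTCTGGATCGAGGA, had 47537 AGO2 mock and 207475 AGO2 R2 reads, against 3 and 2 in AGO1. It begins with G. These were singled out after their values were seen.

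Unlisted sequences with at least 500 reads in the AGO2 libraries numbered 1545, of which 1367 began with A. Of these 1545, 603 were at least 2-fold higher and 7 at least 2-fold lower in R2, with a median ratio of 1.79. Scaled without adaptor reads and miR159b-3p, which was chosen after the data were seen, 185 were higher and 97 lower, with a median of 0.912. The 5 with the highest ratios had 1 or 0 mock reads in AGO2 and are not given as sequences, as their organism could not be told without a genome. Of the 5 lowest, TTGAAAGTGACTACATCGGGG, a form of miR161.1 shifted by 1 base, had a ratio of 0.330 (0.325 to 0.335), and TGTCGAGTAGACCTTGTTGT a ratio of 0.404 (0.355 to 0.461). The other 3, AAACGGATTGGCTCTGAGGGC, ATCCTGCGATCTCTTTGGATT and TTGCAAGTGACTACATCGGGG, had a C for A at position 4 of abundant sequences, and ratios of 0.0150, 0.0136 and 0.000631. Over all parent sequences checked, A4C reads were 5.63% of parent reads in AGO2 mock, against 0.0372% in AGO2 R2, 0.381% in AGO1 mock and 0.452% in AGO1 R2.

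The family test of miR159 and the test of scaling were chosen after the result was seen, and the other tests before their values were computed, although A-start forms of miR850 had been seen by then. A first pattern was that miR159b-3p, a U-start guide, held most AGO2 mock reads. Copying errors as the source of the miR159a reads (TTTGGATTGAAGGGAGCTCTA would be such a copy) were argued against, if they gave each base alike, since reads with C or G as last base were at most 0.108 times the miR159a reads. Errors that favour a particular base and library, as in the changed sequences above, would escape this test. For loading by the first bases, which both miRNAs share, the test was the ratio of miR159b-3p to miR159a. It was 109.6 times higher in AGO2 than in AGO1 in mock and 66.5 times in R2. Both miRNAs differ only in the last base, and the AGO1 and AGO2 libraries carried different adaptors at that end. An effect of the adaptor on this base was not tested, and a clone of miR159b-3p would also raise the ratio. The test therefore cannot decide on loading by the first bases. A single clone or synthetic RNA stays open, as the exact 21-nt share was 99.3% in AGO2 mock, above the 98.1% of the highest other, and 98.5% in AGO2 R2, below the 98.9% of the highest other. In AGO1 the share of miR159b-3p was 57.0% in mock and 51.9% in R2, with 108642 and 104963 miR159a reads counted as other forms. Its 20-nt reads were 8.34% of its 21-nt reads in AGO1 mock and 0.0152% in AGO2 mock. No other biological explanation was tested.

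A second pattern was that 32 of 35 AGO2 sequences had R2 to mock ratios above 1. A candidate explanation is the lower miR159b-3p share in R2, which raises the share of all other small RNAs. Without adaptor reads and miR159b-3p the median log2 ratio was -0.10, against 0.87 with them. Dividing by the total of the other small RNAs tends by construction to bring their ratios toward 1. The lower median is thus no independent test of the explanation. This leaves open which of the 2 scalings is nearer to amounts per cell, since the libraries held no spike-in named in the sources used here.

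Another pattern was the A-start forms, for which sorting by the 5-prime base is a candidate explanation. The share of A starts was higher in AGO2 for 10 of 12 sequences in mock (83.3%) and 22 of 26 in R2 (84.6%). The test was first counted only where the exact intervals were apart, which gave 10 of 12 (83.3%) and 19 of 26 (73.1%), under the 80% set beforehand in R2. The plain count was taken after that. Beyond both intervals 0 sequences were lower in mock and 1 in R2, and all 4 counts lay above the 60% set for absence. The 73.1% (52.2 to 88.4) lay between the 2 limits, so the explanation stays open. Some of the 26 could hardly inform the test. The A-listed miR390a,b-5p and miR391-3p were at 99.8% and 100% in AGO1 R2. For miR158a-3p and miR396b-3p, 71 of 72 and 183 of 184 A starts in AGO2 R2 were unshifted reads with a changed first base. Among sequences not listed with A, 7 of 9 in mock (77.8%) and 17 of 21 in R2 (81.0%) were higher beyond both intervals.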
